A study of Mus musculus with 9 samples.

How the data were processed

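RNA from bone-marrow-derived macrophages of wild-type C57BL/6 mice was measured on 9 expression arrays, 3 in each of 3 groups. Per the labels, marrow cells grew for 7 days in medium with 10% serum and macrophage colony-stimulating factor (M-CSF). The growth protocol gives its concentration as 10 ng/ml and the series text as 20 ng/ml, and neither is tied to particular arrays. All cells then received interleukin 4 (IL-4) at 20 ng/ml for 24 h. The groups received vehicle, LCN2 (lipocalin 2) on day 7 at a dose the labels do not state, or 150 ng/ml recombinant mouse LCN2 from day 0. RNA was isolated on columns and amplified with a kit for small inputs before labelling with biotin. The labels do not say whether the 3 arrays of a group came from separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

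The deposited table holds log2 expression levels for 22203 probe sets on 9 arrays, with 0 missing values. The submitters' processing notes name the R package oligo and the RMA method, with no versions. RMA as the authors ran it corrects background, makes the probe distributions of the arrays alike and summarises the probes of each probe set on the log2 scale. The values were used as deposited. Of the probe sets, 19572 carried 1 gene symbol, 0 carried several and 2631 carried none. All 19572 named probe sets were matched by Entrez identifier to the mouse RefSeq annotation of the GRCm38.p6 assembly, which changed 0 symbols. For the 55 genes with more than 1 probe set, the probe set with the highest mean over the 9 arrays was kept. Probe sets whose mean over all arrays lay below the median of all probe-set means (5.66 on the log2 scale) were left out as dim, which left 10042 genes. Array data carry no counts, so the number of arrays limits the precision.

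Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 9 arrays in 1 fit, and moderated variances without trend. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The comparisons were LCN2 from day 7 against vehicle, LCN2 from day 0 against vehicle, the 2 LCN2 groups against each other, and the mean of both LCN2 groups against vehicle. A moderated F test over the 3 groups was added. The fit and the list test were tested on simulated data with known changes. A list of 24 genes shifted by 0.25 (log2) was called in 100% of 20 data sets, and 0% of unchanged lists were. Those genes varied independently, whereas type I interferon genes correlated at 0.534 on the real arrays. The simulation therefore does not check the list test for correlated genes. For single genes, 200 of 10042 were changed in each data set, in equal shares by 1.25-, 1.5-, 2- and 3-fold. Recovery with independent noise at the residual spread of these arrays was 87.6% for 3-fold, 68.7% for 2-fold, 26.2% for 1.5-fold and 0.7% for 1.25-fold changes. That spread takes in differences between the replicate numbers, which cancel between the real groups, so these shares need not hold for the real arrays. With the replicate number in the model the shares were 97.5%, 81.7%, 48.9% and 3.7%, in the same order.

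Before the data were examined, 38 lists of genes were fixed. They cover macrophage activation, interferon responses, iron and lipid handling, metabolism, stress, proliferation and markers of other cell types of the marrow. The 33 lists with at least 5 tested members were compared with all other genes by limma's camera, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. Camera was also run with the correlation estimated from the data, and fry was run as a test of whether the genes of a list move, on balance, one way. Counts of members past the threshold are given over all genes and adjusted over the list alone. Every difference is the first group named minus the second.

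The array titles number the replicates of each group from 1 to 3. To see whether equal numbers mark arrays handled together, each array's deviation from its group mean was correlated across genes with those of the other groups. All 9 correlations between arrays of the same number exceeded 0.1 (0.16 to 0.82), so the number was taken to pair the arrays. Between numbers 2 and 3 this check could not tell pairs apart, because both deviate from a group mean that the outlying array numbered 1 pulls away. Arrays of number 2 and number 3 from different groups correlated too, at 0.20 to 0.69. Only 5 of 9 arrays, among them all those numbered 1, correlated best with an array of their own number. The difference of number 2 minus number 3 correlated between groups at 0.29, -0.11 and -0.39, so pairing of these 2 numbers is not shown and same-number pairs rest on the titles there. The fit with the replicate number as a block was therefore an alternative, and its values are given where they change a call or move a count by more than 1.5-fold. Unless stated otherwise, standard errors of group differences come from the fit without a block, so they take in differences between the replicate numbers.

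The alternatives fixed beforehand were no filter on dim probe sets, filters at the lower or the upper quartile of probe-set means, a further quantile normalization, centring of each array on its median, the mean of a gene's probe sets, every probe set on its own, moderated variances with trend and robust fitting, array weights, the replicate number as a block, only the compared groups in the fit, a minimum change of 1.5-fold, and omission of each array in turn. Added after the data were seen were the arrays numbered 2 and 3 only, a block with 2 levels (number 1 against the others), the estimated correlation and fry with the replicate block, and the correlation of effects from different replicate numbers. Named genes followed a rule fixed beforehand. It takes the genes past the threshold with the largest changes (or, where fewer than 10 pass, the 10 with the smallest p, named as not past it), the 2 members with the largest change of each list described, and a fixed set of genes of LCN2 biology, IL-4 activation, inflammation and iron handling. Probe sets without a symbol were tested apart. Python 3.11.15 and matplotlib 3.10.9 drew the figures.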

Results

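Gene expression was measured in mouse macrophages that IL-4 had driven toward the anti-inflammatory state often called M2. The treatment was LCN2, a secreted protein that binds bacterial siderophores and so withholds iron. Vehicle, LCN2 from day 7 and LCN2 from day 0 were each measured on 3 arrays. The 9 arrays had like distributions, with medians between 5.60 and 5.69 and values between 2.51 and 13.49 on the log2 scale. The IL-4 target genes Arg1, Retnla, Chil3 and Mrc1 were bright in all groups, with group means between 11.4 and 12.3, while Il1b, an inflammatory cytokine, stayed among the dim genes at 3.81 to 4.23.

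The arrays with replicate number 1 stood apart from the others in every group. The first principal component took 62.5% of the variance and separated the arrays numbered 1 from those numbered 2 and 3, and 3333 of 10042 genes differed between them (1109 higher and 2224 lower on the arrays numbered 1). Proliferation genes took part: 46 of 49 cell cycle genes were lower on the arrays numbered 1, with a median of -1.06 (adjusted p = 3.77e-16, and adjusted p = 0.346 with an estimated correlation). Between the arrays numbered 2 and those numbered 3, limma called 0 genes (310 at an unadjusted p under 0.05). Each group holds 1 array of each number.

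**Figure D1:**
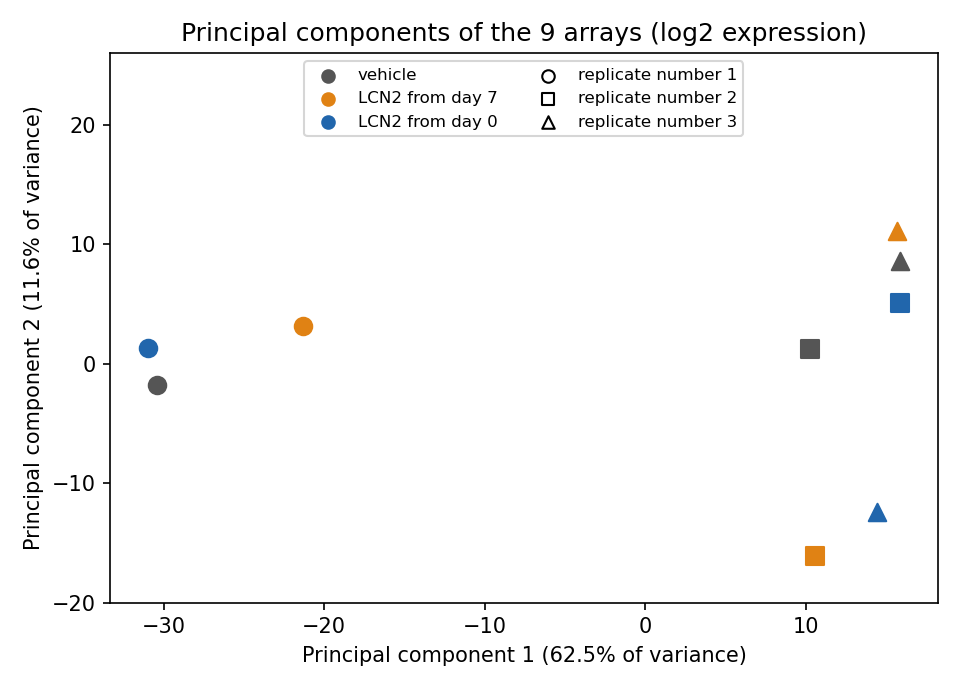
Principal components of the 9 arrays from log2 expression, with component 1 (62.5% of variance) on the x axis and component 2 (11.6%) on the y axis; colours mark the groups and shapes the replicate numbers. The 3 arrays numbered 1 lie at -31.0 to -21.3 on component 1, and the other 6 arrays at 10.3 to 15.9.

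The comparison of LCN2 from day 7 with vehicle asks what LCN2 changed in cells that had already become macrophages when IL-4 was added. Genes of the type I interferon response, the antiviral programme, were lower with LCN2, with a median of -0.24 and a mean of -0.23 on the log2 scale and 22 of 24 genes below 0 (limma camera, adjusted p = 2.42e-09, and adjusted p = 0.787 with an estimated correlation). Ifit3, an interferon-induced antiviral gene, differed by -0.54 ± 0.18 (SE, n = 3 per group), and Zbp1, which encodes a sensor of Z-form nucleic acids, by -0.49 ± 0.14. Over the replicate numbers 1, 2 and 3, the mean of the list differed by -0.23, -0.40 and -0.05. None of its members passed over all genes, and 0 of 24 passed when adjusted over the list alone (1 with the replicate number as a block). It was the only list of 33 past the threshold. IL-4 activation genes had a median of -0.048 (adjusted p = 0.619), with Ccl17 at -0.36 and F13a1 at 0.25. Inflammatory genes had a median of 0.003, with a mean of -0.016 and a test that both pointed down (adjusted p = 0.941), and their most different members were Cxcl3 at -0.35 and Bcl3 at -0.33. Iron handling genes had a median of -0.007 and a mean of 0.028 (adjusted p = 0.679). Median and mean also lay on opposite sides of 0 for glycolysis genes (0.005 and -0.002), for unfolded protein response genes (-0.005 and 0.015) and for NRF2 target genes (0.015 and -0.008), none of which passed.

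With the replicate number as a block, 5 lists passed in place of 1, each at an adjusted p of 0.873 with an estimated correlation. Cell cycle genes were higher (median 0.14, 43 of 49 above 0, adjusted p = 1.73e-05), with Cdc20 at 0.50 and Tk1 at 0.31. Their mean difference was 0.37 within number 1, and 0.047 and -0.010 within numbers 2 and 3. Markers of monocytes, the precursors of macrophages, were higher (median 0.055, mean 0.17, adjusted p = 0.00655), with Plac8 at 0.72 and Ly6c2 at 0.67, and 3 of 14 passed when adjusted over the list alone. Neutrophil granule genes were higher (median 0.25, adjusted p = 0.0156), with S100a8 at 0.64 and Mpo at 0.46. Their mean difference was 0.54, -0.090 and 0.22 within numbers 1, 2 and 3. MHC class II genes were lower (median -0.13, 8 of 9 below 0, adjusted p = 0.0457), with H2-DMa at -0.32 and H2-Aa at -0.17. Their mean difference was -0.36 within number 1 and -0.019 and 0.032 within numbers 2 and 3. The interferon list passed in this fit too (adjusted p = 7.88e-10).

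For single genes, limma called 0 of 10042 between LCN2 from day 7 and vehicle, with 70 genes at an unadjusted p under 0.05 where exchangeable arrays would give 502. The blocked fit called 0, with 259 at an unadjusted p under 0.05, and its lowest adjusted p was 0.353, that of Plac8. The 10 genes with the smallest p, none past the threshold (adjusted p of 1 each), were Phxr4 at 0.61, Ap4s1 at 0.46, Dapk2, a calcium-regulated kinase, at 0.37, Zfp128 at -0.51, the transcription factor gene Sox9 at -0.50, Nadsyn1, an enzyme of NAD synthesis, at -0.41, Llgl2 at -0.44, Ppp1r3d at -0.37, and the interferon genes Ifit3 and Zbp1. The 2 groups did not overlap for 318 genes (3.17%, where exchangeable arrays would give 10%), and the 3 same-number pairs differed in the same direction for 21.7% of genes, where chance gives 25%. The arrays are not exchangeable, since each group holds 1 outlying array numbered 1. This makes full separation of groups rarer, and the fit without a block counts the number shift as spread. Counts under 502 genes or 10% therefore do not show fewer differences than chance. Without LCN2 day 7 replicate 1 the interferon call ended (median -0.019, adjusted p = 0.0658, against 9.48e-14 to 0.0658 over 21 alternatives with the preset correlation). In place of 1, the count of lists was 8 without vehicle replicate 2, 4 without vehicle replicate 1, vehicle replicate 3, LCN2 day 7 replicate 1 or LCN2 day 0 replicate 1, and 2 without LCN2 day 7 replicate 3.

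The comparison of LCN2 from day 0 with vehicle asks what LCN2 changed when it was present from the start of differentiation. MHC class II genes, which present antigen to helper T cells, were lower in the cells grown with LCN2, with a median of -0.49 and a mean of -0.45, and all 9 genes lay below 0 (adjusted p = 6.43e-12, and adjusted p = 0.153 with an estimated correlation). H2-Ab1, a chain of the class II molecule itself, differed by -0.67 ± 0.25 (SE, n = 3 per group) from 10.46 ± 0.43 (SD) with vehicle to 9.78 ± 0.36 with LCN2. H2-Eb1, another chain, differed by -0.61 ± 0.34. With the replicate number as a block, the SE was 0.118 for H2-Ab1 and 0.155 for H2-Eb1. The genes H2-DMa (-0.58 ± 0.15), H2-DMb1 (-0.49 ± 0.14) and H2-DMb2 (-0.38 ± 0.12), whose products load peptide onto class II molecules, were the 3 of 9 past the threshold when adjusted over the list alone; H2-DMb1 and H2-DMb2 are named here after their values were seen, and 0 passed over all genes. With the replicate number as a block, 6 of 9 passed when adjusted over the list alone. The list mean differed by -0.56, -0.45 and -0.34 within replicate numbers 1, 2 and 3. These 5 genes lie between positions 34119693 and 34316674 of chromosome 17.

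Interferon genes were lower as well. All 24 type I interferon genes lay below 0, with a median of -0.23 and a mean of -0.29 (adjusted p = 1.25e-09, and adjusted p = 0.359 with an estimated correlation). Rsad2, which encodes the antiviral enzyme viperin, differed by -0.72 ± 0.23 and Ifit3 by -0.58 ± 0.18. Of the interferon gamma response genes, which include the guanylate-binding proteins, 13 of 14 lay below 0 (median -0.12, adjusted p = 0.000389, and adjusted p = 0.153 with an estimated correlation), with Igtp at -0.43 and Ciita, the master regulator of MHC class II transcription, at -0.43. In these lists 0 genes passed when adjusted over the list alone, and 1 type I interferon gene did with the replicate number as a block.

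Marker genes of several other cell types differed as well, in lists that share members. H2-Aa is also in the MHC class II list and Irf4 in the IL-4 list. Elane and Mpo are in both the neutrophil and the progenitor list. Of the 11 dendritic markers outside the MHC class II list, only 2 are in no other list. Dendritic cell markers were lower (median -0.29, 8 of 12 below 0, adjusted p = 0.00922, and adjusted p = 0.153 with an estimated correlation), with H2-Aa at -0.59 and Irf4 at -0.48. Osteoclast and giant cell markers were lower (median -0.17, mean -0.34, 10 of 12 below 0, adjusted p = 0.0152, and adjusted p = 0.359 with an estimated correlation). Dcstamp (-0.87 ± 0.19) and Ocstamp (-0.87 ± 0.43) encode membrane proteins needed for the fusion of such cells, and Dcstamp was the 1 member past the threshold when adjusted over the list alone. With the replicate number as a block, 3 osteoclast markers, 2 dendritic cell markers and 2 monocyte markers passed in this way. Monocyte markers were higher (median 0.16, 12 of 14 above 0, adjusted p = 0.0152, and adjusted p = 0.359 with an estimated correlation), with Ly6c2 at 0.70 and Plac8 at 0.36. Neutrophil granule genes were higher (median 0.40, 10 of 13 above 0, adjusted p = 0.0152, and adjusted p = 0.436 with an estimated correlation), with Elane at 0.60 and with Mmp9, a protease that osteoclasts also make, at -0.67. Progenitor markers were higher (median 0.058, mean 0.20, 8 of 9 above 0, adjusted p = 0.0152, and adjusted p = 0.359 with an estimated correlation), with Elane at 0.60 and Mpo at 0.60. Without vehicle replicate 1 all 5 calls ended: the medians were -0.008 for osteoclast markers (adjusted p = 0.749, range 1.64e-05 to 0.749 over the alternatives), 0.019 for monocyte markers (0.112, range 1.21e-05 to 0.158), -0.087 for neutrophil genes (0.5, range 7.84e-05 to 0.5), 0.008 for progenitor markers (0.108, range 0.00615 to 0.293) and -0.27 for dendritic cell markers (0.0957, range 0.00219 to 0.283). That omission leaves the replicate numbers unbalanced. On the arrays numbered 1, against the others, the medians were 0.354 for osteoclast markers, -0.395 for monocyte markers and -1.053 for neutrophil genes. Within each number the list means were lower with LCN2 for osteoclast and dendritic markers and higher for monocyte, neutrophil and progenitor markers. The replicate block kept all 5 calls with the preset correlation. The osteoclast and monocyte calls also ended without LCN2 day 0 replicate 2 (medians -0.096 and 0.11, adjusted p = 0.148 and 0.111) or 3 (-0.078 and 0.073, adjusted p = 0.223 and 0.158). So did the neutrophil call, without replicate 2 (median 0.061, adjusted p = 0.196) or 3 (0.161, 0.126). The progenitor call ended without LCN2 day 0 replicate 1 (median 0.325, adjusted p = 0.0617) or 2 (0.248, 0.111), and the dendritic call without replicate 1 (-0.143, 0.0617). Macrophage markers had a median of -0.010 and a mean of 0.017 (adjusted p = 0.688), with Cd81 at 0.41 and Cd14 at 0.31.

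Cholesterol synthesis genes were lower after LCN2 from day 0 (median -0.12, 17 of 20 below 0, adjusted p = 0.0152, and adjusted p = 0.813 with an estimated correlation), with Cyp51 at -0.37 and Hmgcs1 at -0.35. Without vehicle replicate 1, which leaves the replicate numbers unbalanced, their median was 0.006 (adjusted p = 0.4, range 0.000178 to 0.896 over the alternatives). NRF2 targets, genes of the antioxidant response, were higher (median 0.069, 16 of 21 above 0, adjusted p = 0.0211, and adjusted p = 0.359 with an estimated correlation), with Gstm1, a glutathione transferase, at 0.41 and Gclm, a subunit of the enzyme that starts glutathione synthesis, at 0.36. Without LCN2 day 0 replicate 1 the NRF2 median was -0.014 (adjusted p = 0.922, range 0.00115 to 0.922 over the alternatives). IL-4 activation genes had a median of -0.11 and did not pass (adjusted p = 0.401), with Irf4 at -0.48 and Ctsk at -0.42. Inflammatory genes did not pass either (median -0.013, mean 0.015, adjusted p = 0.401), with Ptgs2 and Cd14 each at 0.31, nor did iron handling genes (median 0.016, adjusted p = 0.254), with Slc40a1 at 0.58 and Lcn2 at 0.40. The median and the test also pointed apart, without passing, for the phagocytosis, IL-10 type regulation and chemokine receptor lists (medians -0.007, -0.045 and -0.016, tests upward), and median and mean for the lysosome and unfolded protein response lists.

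In this comparison limma called 0 of 10042 genes, with 142 at an unadjusted p under 0.05 where exchangeable arrays would give 502, and the blocked fit called 0 with 497. The 10 genes with the smallest p, none past the threshold (adjusted p of 0.999 each), were Taf7, a subunit of the general transcription factor TFIID, at -0.62, Nes, which encodes the intermediate filament nestin, at -0.60, Inpp5f, a phosphoinositide phosphatase, at -0.66, Dcstamp at -0.87, Ift88, an intraflagellar transport gene, at 0.61, H2-DMa at -0.58, the mitochondrial carrier gene Sfxn2 at -0.45, the growth factor receptor gene Fgfr1 at -0.69, the chromatin regulator gene Jarid2 at -0.41 and the pseudouridine synthase gene Pus3 at -0.54. The 2 groups did not overlap for 551 genes (5.49%, where exchangeable arrays would give 10%, which these are not), and the 3 same-number pairs differed in the same direction for 27.2%, where chance gives 25%. The calls of the MHC class II and type I interferon lists held in all 21 alternatives with the preset correlation, and the other 8 were each lost in at least 2. Over these alternatives the median ran from -0.579 to -0.294 for MHC class II and from -0.401 to -0.121 for type I interferon genes. A lost call need not mean a smaller shift. The interferon gamma list, at -0.122 with all arrays, was lost at -0.184 without vehicle replicate 1 (adjusted p = 0.0524) and at -0.157 without LCN2 day 0 replicate 2 (0.0765). In place of 10, the count of lists was 14 without vehicle replicate 2, 13 without LCN2 day 0 replicate 1, 12 without vehicle replicate 3, 8 without vehicle replicate 1 or LCN2 day 0 replicate 3, and 5 without LCN2 day 0 replicate 2. It was 10 with the replicate number as a block.

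**Figure D2:**
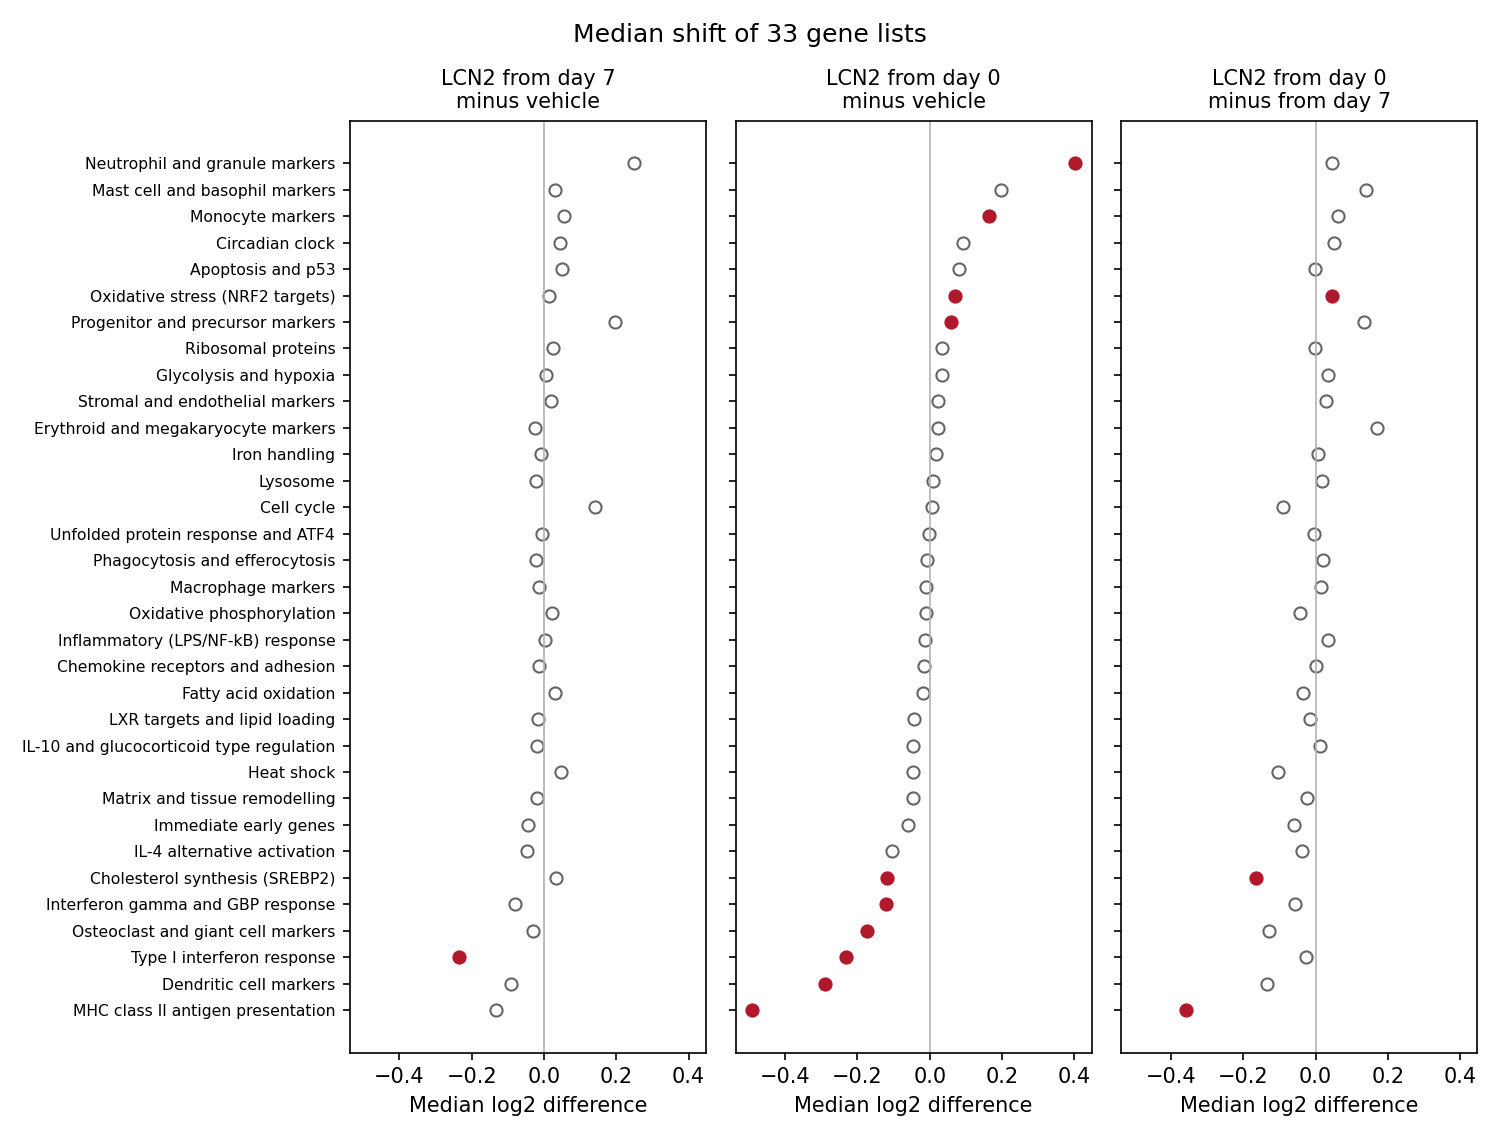
Median log2 difference (x axis) of the tested members of each of 33 gene lists (y axis) in the comparisons of LCN2 from day 7 with vehicle, LCN2 from day 0 with vehicle and the LCN2 groups with each other; filled points passed an adjusted p of 0.05 in limma's camera with a preset correlation, and 0 passed with an estimated one. MHC class II genes lie lowest after LCN2 from day 0, at -0.49 against vehicle and -0.36 against LCN2 from day 7.

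The comparison of the LCN2 groups with each other is the test of the difference between their effects against vehicle. It sets 150 ng/ml from day 0 against a dose from day 7 that the labels do not state. They also do not say whether LCN2 stayed in the medium during IL-4, so time, dose and exposure are not separated. MHC class II genes were lower with LCN2 from day 0 than from day 7, with a median of -0.36 and all 9 genes below 0 (adjusted p = 9.17e-07, and adjusted p = 0.863 with an estimated correlation). H2-Ab1 differed by -0.54 ± 0.25 (SE, n = 3 per group) and H2-Eb1 by -0.51 ± 0.34, and the list mean differed by -0.20, -0.43 and -0.38 within numbers 1, 2 and 3. Cholesterol synthesis genes were lower (median -0.17, 18 of 20 below 0, adjusted p = 0.0038, and adjusted p = 0.863 with an estimated correlation), with Insig1, a brake on sterol synthesis that sterol regulators induce, at -0.32 and Hmgcs1 at -0.29. NRF2 targets were higher (median 0.045, 16 of 21 above 0, adjusted p = 0.0412, and adjusted p = 0.863 with an estimated correlation), with Me1 at 0.45 and Gstm1 at 0.35. In these 3 lists 0 genes passed when adjusted over the list alone, and 5 of 9 MHC class II genes did with the replicate number as a block. The type I interferon list did not differ past the threshold (median -0.026, adjusted p = 0.568), with Mx1 at -0.47 and Stat2 at -0.35. Immediate early genes (median -0.061, adjusted p = 0.882) and unfolded protein response genes (median -0.003, adjusted p = 0.733) had medians below 0 with tests that pointed up, and the medians and means of the phagocytosis, lysosome and p53 lists differed in sign. With the replicate number as a block, osteoclast and giant cell markers were lower too (median -0.13, 11 of 12 below 0, adjusted p = 0.000538, and adjusted p = 0.552 with an estimated correlation), with Dcstamp at -0.77 and Acp5, the osteoclast phosphatase, at -0.73, and 3 of 12 passed when adjusted over the list alone in that fit.

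Between the LCN2 groups limma called 0 of 10042 genes, with 177 at an unadjusted p under 0.05 where exchangeable arrays would give 502, and the blocked fit called 0 with 539. Those with the smallest p, none past the threshold (adjusted p of 1 each), were Taf7 at -0.67, Nes at -0.54, Jarid2 at -0.50, Sfxn2 at -0.48, Dcstamp at -0.77, Dstyk, a protein kinase gene, at -0.58, Ppp1r3d, which targets a phosphatase to glycogen, at 0.55, the calpain gene Capn12 at 0.54, Rnf207 at 0.58 and the tetraspanin gene Tspan9 at 0.49. The 2 groups did not overlap for 502 genes (5%, where exchangeable arrays would give 10%, which these are not), and the 3 same-number pairs differed in the same direction for 20.9%, where chance gives 25%. The cholesterol call ended without LCN2 day 7 replicate 1 (median -0.027, adjusted p = 0.943) and without LCN2 day 0 replicate 2 (-0.187, 0.0634) or 3 (-0.116, 0.245), over a range of adjusted p of 1.79e-05 to 0.943. The NRF2 call ended without LCN2 day 0 replicate 1 (median -0.028, adjusted p = 0.916), LCN2 day 7 replicate 3 (0.023, 0.517) or vehicle replicate 3 (0.045, 0.0503), over a range of 0.00101 to 0.916. The cholesterol shift without LCN2 day 0 replicate 2 and the NRF2 shift without vehicle replicate 3 were thus no smaller than with all arrays (-0.165 and 0.045). The count of lists was 10 without LCN2 day 0 replicate 1, 7 without LCN2 day 7 replicate 1 and 5 without LCN2 day 7 replicate 2, in place of 3.

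**Figure D3:**
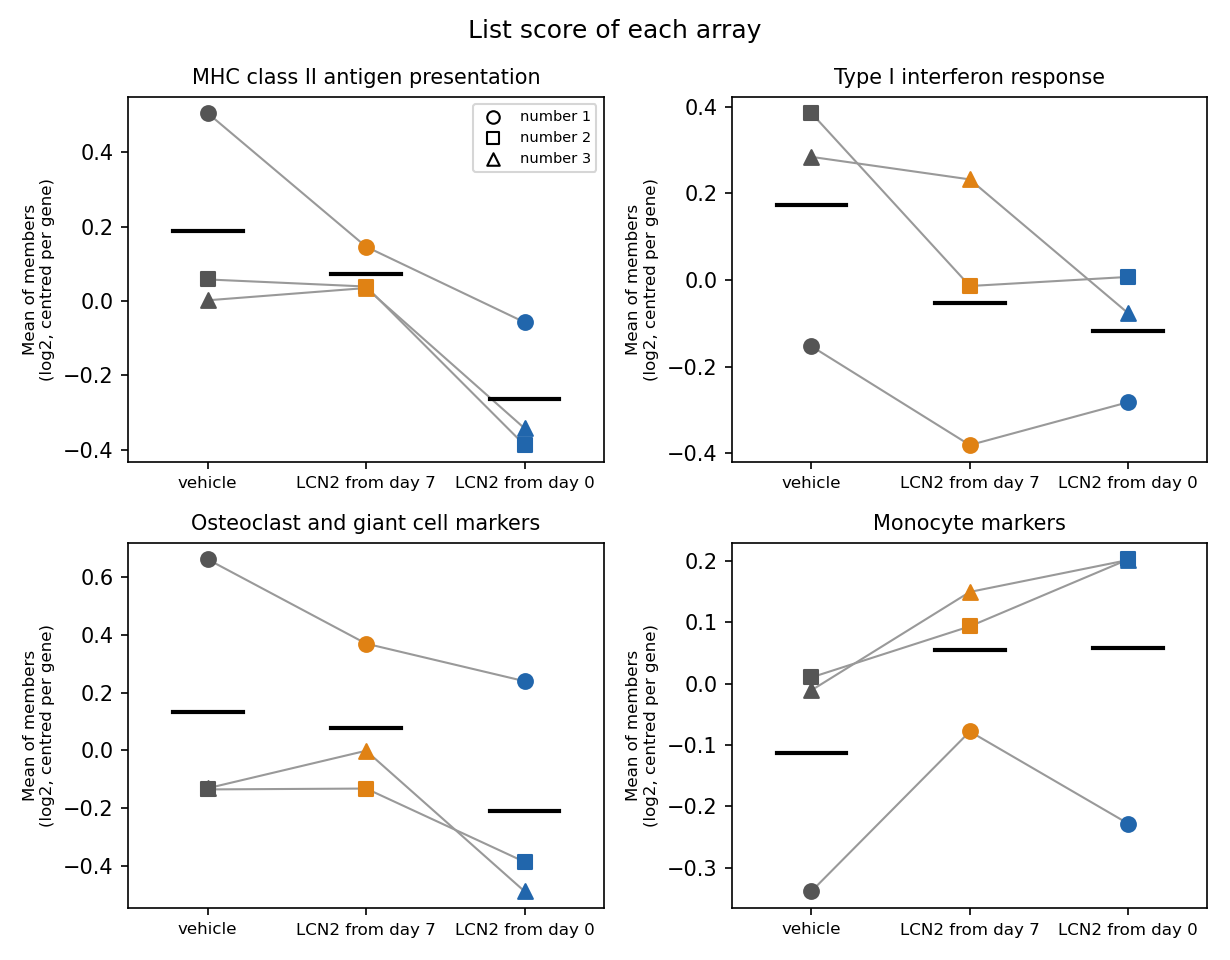
Mean of the members of 4 gene lists on each array (y axis, log2, each gene centred on its mean over the 9 arrays) by group (x axis); lines join arrays of the same replicate number, shapes mark the number and bars the group means. The MHC class II score falls from vehicle to LCN2 from day 0 along all 3 lines, from 0.51 to -0.057 for number 1, from 0.058 to -0.39 for number 2 and from 0.002 to -0.34 for number 3.

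The mean of both LCN2 groups was compared with vehicle, which a difference in 1 of the groups can move. All 24 type I interferon genes lay below 0 (median -0.22, adjusted p = 8.22e-13, and adjusted p = 0.39 with an estimated correlation), and so did all 9 MHC class II genes (median -0.31, adjusted p = 7.8e-09, and adjusted p = 0.251 with an estimated correlation). Interferon gamma response genes (median -0.11, adjusted p = 0.000366) and dendritic cell markers (median -0.21, adjusted p = 0.00952) were lower as well, both at an adjusted p of 0.251 with an estimated correlation. Monocyte markers (median 0.11, adjusted p = 0.00907), neutrophil granule genes (median 0.33, adjusted p = 0.0199) and progenitor markers (median 0.13, adjusted p = 0.0459) were higher, at adjusted p of 0.372, 0.499 and 0.423 with an estimated correlation. Of these 7 lists, the type I interferon list alone passed with LCN2 from day 7 in the fit without a block. There MHC class II genes stood at an adjusted p of 0.0868, dendritic cell markers at 0.218 and progenitor markers at 0.552. Without vehicle replicate 1, which leaves the replicate numbers unbalanced, the medians of the neutrophil and progenitor lists were -0.11 (adjusted p = 0.76, range 0.000155 to 0.76 over the alternatives) and -0.039 (0.223, range 0.00875 to 0.462). The progenitor call held in 7 of 20 alternatives. In these 7 lists 0 genes passed when adjusted over the list alone, while 5 MHC class II genes, 2 dendritic cell markers, 2 monocyte markers and 1 type I interferon gene did with the replicate number as a block. With the replicate number as a block 12 lists passed. The 5 added were IL-4 activation genes, lower with a median of -0.077 (adjusted p = 0.0243), immediate early genes, lower with a median of -0.074 (0.0488), osteoclast and giant cell markers, lower with a median of -0.14 (0.000451), cell cycle genes, higher with a median of 0.079 (0.000668), and p53 and apoptosis genes, higher with a median of 0.042 (0.0391). With an estimated correlation in the blocked fit these stood at adjusted p of 0.529, 0.529, 0.448, 0.784 and 0.468.

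For this comparison limma called 0 of 10042 genes, with 68 at an unadjusted p under 0.05 where exchangeable arrays would give 502, and the F test over the 3 groups called 0 with 97. The blocked fits called 0 as well, with 312 and 406. In place of 7, the count of lists was 13 without vehicle replicate 2 or 3, 11 without LCN2 day 7 replicate 1 and 4 without LCN2 day 0 replicate 3. Across genes, the log2 differences of the LCN2 groups from the shared vehicle arrays correlated at 0.42, with the same sign for 63.3% of genes. Simulated groups that did not differ gave 0.5 and 66.7%, because both differences use the same vehicle arrays. When the vehicle arrays were split between the comparisons, the correlation was -0.36 on average, between -0.53 and -0.19 over 6 splits. Each split unbalances the replicate numbers, and simulated groups that did not differ gave -0.33 with the number shifts of these arrays and 0 without them, so this value does not show opposed effects. An effect of LCN2 from day 7 within 1 number and an effect from day 0 within another share no array, and these correlated at 0.09 on average, between -0.06 and 0.29 over 6 pairs (chosen after the data were seen). Genes are not independent replicates, so no p is attached to these values.

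None of the genes central to LCN2 and to IL-4 activation passed the threshold in either LCN2 group. Lcn2 itself differed by 0.40 ± 0.70 (SE, n = 3 per group) in either group, from a vehicle mean of 9.70 ± 1.27 (SD), and by 0.005 between them. With the replicate number as a block, the SE of these Lcn2 differences was 0.191. The proposed LCN2 receptor genes Slc22a17 and Mc4r lay under the filter, with group means of 5.01 to 5.40 and of 3.30 to 3.40, and Lrp2 did as well at 4.31 to 4.57. Lrp6 had group means of 8.35, 8.41 and 8.48. Arginase 1 (Arg1) differed from vehicle by 0.018 with LCN2 from day 7 and 0.080 from day 0, Retnla by -0.086 and -0.12, Chil3 by -0.063 and 0.18, the mannose receptor gene Mrc1 by -0.048 and 0.15, and the IL-4 receptor gene Il4ra by -0.006 and -0.029. Between the LCN2 groups, day 0 minus day 7, Arg1 differed by 0.062, Retnla by -0.038, Chil3 by 0.24, Mrc1 by 0.20 and Il4ra by -0.023. Tnf differed from vehicle by -0.049 and -0.17 and between the LCN2 groups by -0.12. Il10 had group means of 5.52 to 5.61 and was not tested, being dim.

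No gene of iron handling passed the threshold either. Slc40a1, the iron exporter ferroportin, differed from vehicle by 0.18 ± 0.48 with LCN2 from day 7 and 0.58 ± 0.48 (SE, n = 3 per group) from day 0, and lay above vehicle in 3 of 3 same-number pairs in the latter. Hmox1, which breaks down haem, differed by -0.050 and 0.17, the transferrin receptor gene Tfrc by -0.025 and 0.17, and the ferritin gene Fth1 by 0.012 and 0.028. Between the LCN2 groups, day 0 minus day 7, Slc40a1 differed by 0.39, Hmox1 by 0.22, Tfrc by 0.20 and Fth1 by 0.016. For Lcn2 the 95% interval of the difference of LCN2 from day 0 from vehicle ran from -1.19 to 1.99, and from -0.036 to 0.84 with the replicate number as a block (adjusted p = 0.967). For Slc40a1 it ran from -0.51 to 1.66, and from 0.16 to 0.99 in the blocked fit (adjusted p = 0.96). For Mrc1 it ran from -0.14 to 0.45 and for Fth1 from -0.19 to 0.24.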

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

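Tests chosen only after their results were seen are the counts of genes over splits of the arrays, the tests of dendritic cell markers and of the IL-4 list against the MHC class II list, and the test of a smaller share of macrophages. A first test of dendritic cells with only 2 markers was replaced by one with 11 after its result was seen, and a test of Y-linked genes for the arrays numbered 1 was dropped. A test of a shift in the replicate numbers for the interferon list was dropped too, because each group holds 1 array of each number and such a shift cancels. Medians of 3 lists stood out because the LCN2 groups differed from each other past the threshold: MHC class II genes (day 0 minus day 7, -0.359, adjusted p = 9.17e-07), cholesterol synthesis genes (-0.165, adjusted p = 0.0038) and NRF2 targets (0.045, adjusted p = 0.0412), each at an adjusted p of 0.863 with an estimated correlation. Groups of 3 arrays are too small for a test of single deviant samples.

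Lower MHC class II expression after LCN2 from day 0 is the first pattern. A bias that follows expression level is argued against, since 0% of 10000 lists matched on level shifted as far as the mean of -0.45 (the farthest reached -0.176). Chance is a separate question. Of the 27 ways to pick 1 array per replicate number only 1, the real one, set the list this far apart (-0.393, against 0.299 for the next), although 1.22 of 33 lists would do so by chance and 4 did. The smallest exact p that 27 picks allow is 0.037, and the list was singled out from these same arrays. Fewer dendritic cells cannot be told apart from a change within macrophages: 11 dendritic markers outside the list differed by -0.179 ± 0.066 (SE over 3 numbers) and so by 0.271 ± 0.098 less than the MHC class II list, but only 2 of them are in no other list. A weaker response to IL-4 is also open, because the 10 IL-4 genes in no other list differed by -0.137 ± 0.106, which lies 0.088 ± 0.087 above the bound of -0.225, a fall of 0.5 times that of the MHC class II list. An effect of LCN2 on antigen presentation by the macrophages themselves was not tested apart from these.

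A lower type I interferon response in both LCN2 groups is the second pattern. Level bias is argued against here too (0% of 10000 matched lists, farthest -0.101, against a mean of -0.257). With LCN2 from day 7 the list differed by only -0.052 within number 3, and its call ended without LCN2 day 7 replicate 1 (median -0.019, adjusted p = 0.0658, against 9.48e-14 to 0.0658 over the alternatives). Only 1 of 27 picks set the list as far apart (0.257, against 0.236 for the next), and 3 of 33 lists were most extreme for the vehicle arrays where chance gives 1.22. With these interferon genes correlated at 0.534 in camera's estimate (0.309 with the replicate number as a block), a single difference in interferon tone between the cultures could move all of them at once, which the adjusted p of 0.39 with an estimated correlation (0.298 with the block) leaves open. Whether LCN2 or an unrecorded difference of the vehicle cultures set this level was not tested.

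The third pattern is the distance of the arrays numbered 1 from the others. A curve over expression level took 1.4% of the variance of the difference, so compressed signal left after RMA accounts for little of it. RMA makes the probe distributions of the arrays alike, so compression before that step could not be tested. A smaller share of macrophages that raised the markers of all other cells alike is argued against, because these markers moved apart. A change of share that raised only some cell types cannot be excluded in this way. The neutrophil list had a median of -1.053 (9 of 13 lower, 2 higher) and the erythroid list one of 0.323 (3 of 7 higher, 0 lower), the osteoclast list stood at 0.354 and the stromal list at 0.103, and the macrophage list at 0.127. The monocyte list stood at -0.395 (9 of 14 lower, 4 higher), the progenitor list at -0.176, the dendritic list at -0.124 and the mast cell list at 0.131. A larger share of macrophages on these arrays was not tested. A separate preparation of cells with less proliferation may explain the lower cell cycle genes, and it is confounded with a technical batch, since the labels tie neither to the number. Apart from the share of macrophages, no biological explanation was tested, as the design gives none.

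Other splits of the arrays bear on the counts. For the comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. Where limma called 0 genes in the real split, every split gives as many by construction, so these counts tell nothing about chance: 10 of 10 in each comparison of 3 with 3 arrays (highest other 0), 84 of 84 for both LCN2 groups against vehicle (highest other 3778) and 100 of 100 drawn for the F test (highest other 2903). The counts at an unadjusted p under 0.05 were 70, 142, 177, 68 and 97. For lists, 7 of 10 splits gave as many with LCN2 from day 7 against vehicle (real 1, highest other 15), 5 of 10 with LCN2 from day 0 against vehicle (real 10, highest other 15) and 7 of 10 between the LCN2 groups (real 3, highest other 13). For both LCN2 groups against vehicle chance cannot be excluded, as 44 of 84 splits gave as many lists (real 7, highest other 17). The split that put the 3 arrays numbered 1 together gave the 3778 genes and the 17 lists, which points to the structure by replicate number. Among splits that keep 1 array of each number per group, as the real split does, 1 of 4 gave as many lists for LCN2 from day 0 against vehicle (highest other 3), 1 of 4 between the LCN2 groups (highest other 1), 2 of 4 for LCN2 from day 7 against vehicle (highest other 4) and 3 of 27 for both against vehicle (highest other 8). The split with 8 lists set the 3 arrays of LCN2 from day 0 against all others, so it is itself a treatment comparison. The remaining one, with 7 lists, grouped vehicle replicates 1 and 2 with LCN2 day 7 replicate 3.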

How the results depend on the processing

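Alternatives chosen only after the data were seen are the arrays numbered 2 and 3 only, the 2-level block, the estimated correlation and fry with the replicate block, and the correlation of effects from different replicate numbers. Limma called 0 genes in all 5 tests under every alternative run, at lowest adjusted p of 0.17 (day 7 against vehicle), 0.0893 (day 0 against vehicle), 0.0938 (day 0 against day 7), 0.156 (both against vehicle) and 0.119 (F test), and none of 237 results for named genes passed. Unadjusted p under 0.05 ranged from 10 to 587, 61 to 960, 54 to 597, 22 to 1058 and 38 to 785 genes. The counts of lists past the threshold (1, 10, 3 and 7 in the 4 comparisons, in the same order) were 0 with an estimated correlation and with fry, with or without the replicate block. They were 5, 10, 4 and 12 with the replicate number as a block, and 5, 11, 4 and 12 with the 2-level block. Array weights gave 2, 5, 5 and 2, and their estimation warned that it stopped before converging. The lower quartile as filter gave 4 for day 7 against vehicle and the upper quartile gave 2, with 6 for day 0 against vehicle. The fit of only the compared groups gave 4 for day 7 against vehicle, and the arrays numbered 2 and 3 gave 7 for day 0 against day 7. Leaving out single arrays gave 1 to 8, 5 to 14, 2 to 10 and 4 to 13 lists. The block ended none of the 21 list calls and added 10. Of 21 list calls, 4 held in every alternative with the preset correlation: MHC class II in day 0 against vehicle and day 0 against day 7, and type I interferon in day 0 and in both against vehicle. The other 17 were lost in at least 1, with 13 lost without vehicle replicate 1, 12 with array weights, 9 without LCN2 day 0 replicate 2, 8 without LCN2 day 0 replicate 3, 8 with the arrays numbered 2 and 3 only, 6 without a filter, 5 without LCN2 day 0 replicate 1, 3 without LCN2 day 7 replicate 1, 3 without LCN2 day 7 replicate 3, 2 without vehicle replicate 3, 1 without LCN2 day 7 replicate 2, 3 with the lower quartile as filter, 3 with a further quantile normalization, and 1 each with the upper quartile, median centring and trend with robust fitting. MHC class II for both against vehicle stood at -0.152 (adjusted p = 0.0965, range 3.22e-10 to 0.0965) without vehicle replicate 1, and dendritic markers at -0.204 (0.0778, range 0.00115 to 0.481) without LCN2 day 7 replicate 2. Some list medians turned to the other direction, past the threshold before or after. Cell cycle genes in day 0 against day 7 (-0.089) were 0.165 with array weights and with the arrays numbered 2 and 3 only, and -0.332 to 0.362 over omitted arrays, the highest without LCN2 day 0 replicate 1. In day 0 against vehicle (0.007) they ran from -0.273 without vehicle replicate 1 to 0.527, with -0.191 without LCN2 day 0 replicate 3, and in both against vehicle from -0.252 without vehicle replicate 1 to 0.333. Without vehicle replicate 1 also stood the upper ends of the ranges of cholesterol synthesis genes (-0.222 to 0.006 in day 0, -0.159 to 0.072 in both against vehicle), immediate early genes (-0.198 to 0.166 in both), lysosomal genes (-0.100 to 0.072 in day 7, -0.078 to 0.074 in both) and matrix genes (-0.116 to 0.129 in day 7, -0.081 to 0.096 in both). Without LCN2 day 0 replicate 1 stood the lower ends for lysosomal genes (-0.135 to 0.086 in day 0 against vehicle, -0.107 to 0.078 in day 0 against day 7) and immediate early genes (-0.258 to 0.166 in day 0 against day 7). Medians of called lists also turned without passing: neutrophil genes without vehicle replicate 1 (0.403 to -0.087 in day 0, 0.332 to -0.113 in both against vehicle), progenitor markers without vehicle replicate 1 (0.125 to -0.039 in both), and NRF2 targets without LCN2 day 0 replicate 1 (0.069 to -0.014 in day 0 against vehicle, 0.045 to -0.028 in day 0 against day 7). The correlation of the LCN2 effects was -0.36 with the vehicle arrays split, 0.09 between effects from different replicate numbers and 0.25 to 0.69 over omitted arrays. A split unbalances the replicate numbers, and simulated groups that did not differ gave -0.33 with the number shifts and 0 without them. Omission of 1 array numbered 1 unbalances the replicate numbers as well. On those arrays, against the others, list medians were -1.062 for cell cycle, 0.717 for immediate early, 0.304 for lysosomal, 0.242 for matrix and 0.339 for cholesterol synthesis genes. The turns of these lists without vehicle replicate 1 or LCN2 day 0 replicate 1 went the way that such an imbalance moves them. The cause of the remaining moves was not tested. Il1b, Il10 and Slc22a17 lay under the filter at the median of probe-set means and were not tested there, and background was not measured.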

Other observations

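The endotoxin test and its bound were chosen only after the result was seen, and the gene names below were chosen after their values were seen. Many genes differed between the arrays numbered 1 and the others, and these arrays cannot separate a difference of the cells from one of handling. Ccr2, the receptor that brings monocytes out of the marrow, stood at 6.30 on them and 8.69 on the others, a difference of -2.39 ± 0.081 (SE, adjusted p = 3.97e-06 in limma, n = 3 and 6 arrays). Cd34, a progenitor marker, differed by -2.15 ± 0.13, the neutrophil granule gene Ngp by -1.97 ± 0.17, Phgdh, which starts serine synthesis, by -2.01 ± 0.24 and Asns, which makes asparagine, by -1.94 ± 0.12. Higher on the arrays numbered 1 were Abca1, the cholesterol exporter, at 3.03 ± 0.20, the oxidised lipoprotein receptor gene Olr1 at 3.65 ± 0.17, Mfge8, a bridge to apoptotic cells, at 2.97 ± 0.12, Thbs1 at 2.99 ± 0.36 and the IL-4 target Ccl24 at 2.44 ± 0.18.

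By groups of genes, with members counted where they passed the threshold, immediate early genes (17 of 23 higher and 3 lower, median 0.72, adjusted p = 1.05e-07), lysosomal genes (18 of 32 higher and 2 lower, median 0.30, adjusted p = 2.3e-08), cholesterol synthesis genes (11 of 20 higher and 0 lower, median 0.34, adjusted p = 9.33e-07), IL-4 activation genes (16 of 29 higher and 6 lower, median 0.48, adjusted p = 0.00026) and inflammatory genes (14 of 25 higher and 5 lower, median 0.50, adjusted p = 6.58e-05) were higher as lists on the arrays numbered 1. Type I interferon genes were lower there (12 of 24 lower and 0 higher, median -0.32, adjusted p = 0.00157), as were neutrophil granule genes (9 of 13 lower and 2 higher, median -1.05, adjusted p = 0.0216). With an estimated correlation the adjusted p of these lists lay between 0.27 and 0.418. Y-linked genes (Eif2s3y, Kdm5d and Uty) stood between 2.82 and 3.74 on all arrays, near the lowest values measured.

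Bacterial endotoxin in the LCN2 preparation could raise inflammatory genes. The inflammatory list differed by -0.001 on average between both LCN2 groups and vehicle within the replicate numbers, with an upper 95% limit of 0.073. Without vehicle replicate 1, which leaves the numbers unbalanced, its median was 0.139 for both LCN2 groups against vehicle (adjusted p = 0.0109, range 0.0109 to 0.947 over the alternatives) and 0.134 for LCN2 from day 0 (0.00647, range 0.00647 to 0.913). Endotoxin is left open, as the shift that it would bring was not measured. Of the 2631 probe sets with no gene symbol, 1037 passed the filter and limma called 0 of them in each of the 4 comparisons, with 9, 10, 24 and 5 at an unadjusted p under 0.05.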
